A study of Mus musculus with 12 samples.

How the data were processed

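Small RNA from stem-like mouse medulloblastoma cells (source tissue cerebellum, genotype Math1-Cre; SmoM2) was measured in 12 libraries. Total RNA was extracted with a Qiagen column kit, and small RNA libraries were made from it with a kit whose maker the labels do not name. The libraries form 3 groups of 4, named by the guide in their labels. The sgGal4 control has 1 guide (replicates 1 to 4). Miat knockdown has 2 guides with 2 libraries each (6-1 and 6-2 for sgMiat-6, 96-1 and 96-2 for sgMiat-96), and so does Mtdh knockdown (1-1 and 1-2 for sgMtdh-1, 2-1 and 2-2 for sgMtdh-2). The labels do not say whether the libraries of a guide come from separate cultures, so p-values measure the spread between these libraries, which may be technical.

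The deposited tables give raw counts per RefSeq non-coding transcript, 4529 per library, per the file headers. They also give deposited FPKM values, which the authors scaled per kilobase and per 1000000 counts of the table, since the lengths they imply were whole numbers within 0.001 for 100% of transcripts with counts. The deposited TPM values sum to 1000000 in each library. The authors' notes name STAR with GRCm38 and mm10, without versions. The counter, adapter trimming and treatment of reads with several positions are not given in the sources used here. Counts were used throughout, and FPKM and TPM were not used further.

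The tables hold 1201 miRNA precursors under 1116 symbols, of which 281 had a count in any library and 920 were at 0 in all. miRNA precursors of the same symbol were summed, and each of the tested miRNAs has a single entry. Across all classes 172 repeat another transcript of the same symbol in every library, holding 1.30% to 3.47% of the counts. Miat has 2 such identical entries and was counted once. Total counts per library were 34263 to 65240 in controls, 83544 to 164537 for Miat knockdown and 23318 to 154111 for Mtdh knockdown, and miRNA counts were 2369 to 4568, 1407 to 3921 and 1015 to 7287. Intervals and floors cover counting error only. Where a count was 0, the limit was taken as 3 counts.

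The following choices were made before the data were examined: the groups, the tests, the miRNA lists, the alternatives and the rule for naming miRNAs. miRNA counts were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr by group (minimum count 10, minimum total 15), TMM factors (0.523 to 1.62), and a quasi-likelihood fit with 1 term per group over all 12 libraries. The common dispersion was 0.139, a biological coefficient of variation of 0.373. This left 29 miRNAs, which held 85.0% to 94.4% of the miRNA counts of a library. Contrasts were Miat and Mtdh libraries each against control, and Mtdh against Miat. A second fit with 1 term per guide tested each guide against control and the guides of a target against each other. Benjamini-Hochberg adjustment was applied within each contrast at 0.05, and all tests were two-sided. Levels are TMM-scaled counts per 1000000 counts of the tested miRNAs.

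The overlap of calls was set against independent lists and against 100 simulated data sets with unchanged groups and shared controls. Lists with at least 3 tested members were tested with camera and fry of limma 3.58.1 on voom values, with 8 list tests against the control. The same lists were also tested between Mtdh and Miat libraries. Shares of RNA classes were compared with two-sided exact permutation tests of 4 libraries against 4. Miat rates were compared by an exact conditional interval of counts summed over libraries. Genome positions came from RefSeq and GENCODE annotation of GRCm38. Exact tests and intervals were computed in R. Python 3.11.15 with pandas 2.3.3 was used to join the counts and summarise shares. Libraries of a guide were compared by chi-squared tests with scipy 1.17.1, and matplotlib 3.10.9 was used for plots.

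The miRNAs named for each target were, by rule, those past the threshold: up to 12 with the largest change and no overlap with controls, and up to 8 with the highest mean level. The lowest p-values not past the threshold filled up to 20, and up to 4 members per list, the 5 most abundant miRNAs, Miat and Mtdh were added. Transcripts of other classes named under the other observations were chosen after their values were seen.

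Alternatives tried were other scaling factors (DESeq2 size factors, upper quartile, none), DESeq2 1.42.0, limma-voom with and without guide as a random effect, and other filters on low counts. They also included the guide fit, fits of only 2 groups, a replicate block from the last number of the library name, a fold minimum of 1.5, a robust fit, each library and each guide left out, all classes tested together, and copies of a miRNA summed. Alternatives chosen after seeing the data were leaving out the 3 libraries under 2000 miRNA counts, library totals without Mir30d, leaving out miRNAs at small nucleolar or Cajal body RNA loci, the Rn45s share as a covariate, fry, and leaving out each library for the guides, the overlap and the class shares. Some alternatives tried for the counts of called miRNAs were extended to each named miRNA and to the overlap at that stage. Ratios of both arms of a precursor were planned but not run, since each value counts a whole precursor.

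The test was checked on 50 simulated data sets of 29 miRNAs with the fitted means and dispersions, 4 of them changed in each. For Miat it recovered 29% of 2-fold and 85% of 4-fold changes and called 0.4% of unchanged miRNAs, and for Mtdh 28%, 81% and 0.32%. The simulated libraries were independent, without a term for guides. These rates therefore do not cover libraries nested in guides, as here, where the guide correlation in voom was 0.262. Libraries with the same guide differed by more than counting error in every pair, so none is a copy of another, and each entered the fits as 1 library. This does not show that they are independent cultures.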

Results

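Small RNA libraries from mouse stem-like medulloblastoma cells of the Math1-Cre; SmoM2 genotype were compared between 3 groups of 4 libraries. SmoM2 is an activated form of the Hedgehog signal transducer Smoothened, and Math1-Cre switches it on in the granule neuron lineage of the cerebellum. Control libraries carried sgGal4, a guide against a yeast factor that mice lack. The other libraries carried guides against Miat, a nuclear long non-coding RNA, or against Mtdh, which encodes metadherin, a protein found with the nuclease SND1 and reported in the complex that loads miRNAs. The question was whether depletion of either changes the miRNAs of these cells. Libraries held 23318 to 164537 counts over 4529 RefSeq non-coding transcripts, of which 1015 to 7287 lay on miRNA precursors, so 29 miRNAs had enough counts to be tested. A count of 3, the level a count of 0 allows, stood for 558 to 4838 CPM, TMM-scaled counts per 1000000 counts of those 29 miRNAs.

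The targeted RNA itself was sparse. Small fragments do not measure the level of a long transcript, so these counts show neither depletion nor its absence. Miat was counted 0, 1, 1 and 1 times in the 4 control libraries, 1 and 0 times in the sgMiat-96 libraries, and 49 and 30 times in the sgMiat-6 libraries. Per 1000000 counts of all classes, the rate was 276 with sgMiat-6 (95% exact Poisson interval 219 to 344), 5.96 with sgMiat-96 (0.151 to 33.2) and 15.7 in the control (3.24 to 45.9). The sgMiat-6 rate was 17.6 times the control rate (95% exact interval 5.80 to 87.1, for counting error only), a direction opposite to the group name, so the libraries are called below by their labels. Mtdh encodes a protein, and its transcript is not analysed here.

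Fragments counted on the ribosomal RNA precursor, Rn45s, made up most counts in every group, and their share was higher with Miat and with Mtdh guides. Counts per transcript do not tell fragments of the precursor from those of the mature ribosomal RNAs it contains. Rn45s, the precursor of the 18S, 5.8S and 28S ribosomal RNAs, took 54.4% ± 1.16 of counts in control libraries (SD, n = 4), 73.7% ± 6.06 in those labelled Miat knockdown and 70.5% ± 6.28 in those labelled Mtdh knockdown. The miRNA share was 7.07% ± 0.162 in controls, 2.68% ± 1.09 with Miat guides and 4.48% ± 0.751 with Mtdh guides. Small nucleolar and Cajal body RNAs, which guide the modification of other RNAs, held 15.5% ± 0.396, 9.66% ± 2.41 and 7.96% ± 1.47. The RNA of RNase MRP, an enzyme that cleaves the ribosomal precursor, held 13.3% ± 0.464, 5.50% ± 1.84 and 6.58% ± 1.76. The RNA of RNase P, which matures transfer RNAs, went the other way, at 0.229% ± 0.0479 in controls, 0.990% ± 0.894 with Miat guides and 1.18% ± 0.488 with Mtdh guides. Among the Miat libraries RNase P RNA averaged 0.412% with sgMiat-6 and 1.57% with sgMiat-96, and without Miat 96-1, at 2.30%, the difference from control was 0.325 points in place of 0.761. Each of these 10 differences had a two-sided exact permutation p of 0.0286, the lowest that 4 libraries against 4 can give, and an adjusted p of 0.0312 over 12 such tests. The remaining rows held 9.48% ± 0.562 in controls, 7.50% ± 1.29 with Miat guides (exact p = 0.0286) and 9.29% ± 2.79 with Mtdh guides (exact p = 0.971).

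**Figure D1:**
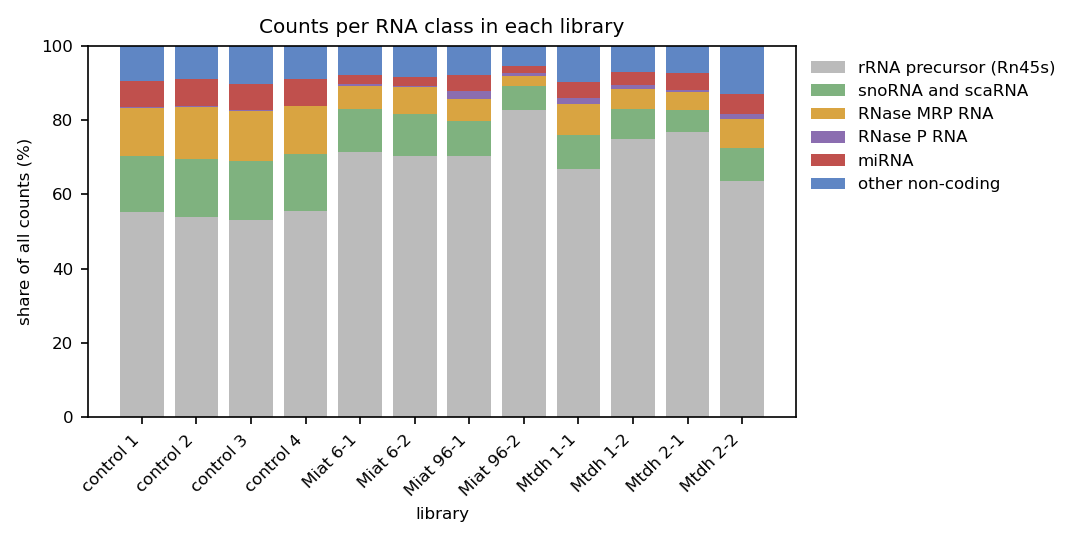
Share of all counts (percent) taken by each class of RNA, with 1 stacked bar per library. The ribosomal precursor Rn45s, at the bottom of each bar, averages 54.4% in controls, 73.7% with Miat guides and 70.5% with Mtdh guides.

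Part of this pattern is arithmetic, since one large class lowers the shares of the others. As a share of the counts outside Rn45s, miRNAs held 15.5% ± 0.367 in controls, 10.1% ± 2.82 with Miat guides (exact permutation p = 0.0286, n = 4, adjusted 0.0357 over 10 tests) and 15.5% ± 3.48 with Mtdh guides (exact p = 1). RNase MRP RNA stayed lower, at 29.2% in controls against 20.4% and 22.1%, and RNase P RNA stayed higher, at 0.502% against 3.85% and 3.90%. In an edgeR fit of all classes scaled by TMM, RNase MRP RNA did not pass. Its log2 fold change there was -0.49 with Miat guides and -0.35 with Mtdh guides. Small nucleolar and Cajal body RNAs held 34.0% in controls, 36.7% with Miat guides (exact p = 0.2) and 27.2% with Mtdh guides. The remaining rows were higher outside Rn45s, at 20.8% in controls, 28.9% with Miat guides and 31.2% with Mtdh guides (exact p = 0.0286 each).

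A single precursor, Mir30d, supplied most miRNA counts of the control cells. The miR-30 family restrains mesenchymal transition and targets many differentiation regulators. Outside Rn45s, Mir30d held 8.32% ± 0.602 of counts in controls, 2.03% ± 0.177 with Miat guides (exact permutation p = 0.0286) and 10.03% ± 3.53 with Mtdh guides (exact p = 0.543). The other miRNAs together held 7.19% ± 0.273, 8.08% ± 2.68 (exact p = 0.886) and 5.51% ± 1.21 (exact p = 0.0571). Mir30d took 53.6% ± 2.69 of miRNA counts in controls (SD, n = 4), 20.9% ± 3.62 in the libraries labelled Miat knockdown and 63.5% ± 10.4 in those labelled Mtdh knockdown. Its share of miRNA counts ran from 15.4% to 22.8% in Miat libraries and from 51.0% to 56.9% in controls. Next in mean level over all 12 libraries came Mir6538, Mir677, Mir6236 and Mir351. In the controls alone Mir351, at 46849 CPM, and Mir181a-1, at 43422 CPM, exceeded Mir6236 and Mir677. Mir6538 and Mir6236 are sparsely studied precursors, and Mir351 belongs to the X-linked Mir322 and Mir503 cluster, which restrains the cell cycle.

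**Figure D2:**
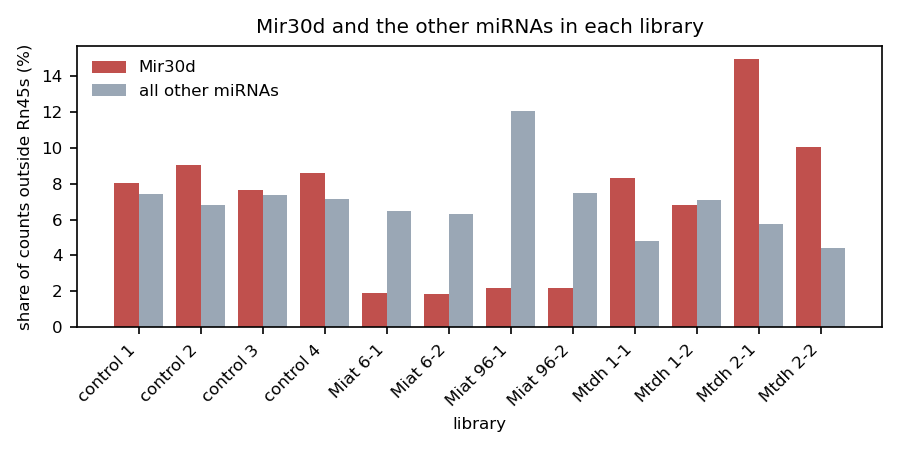
Share of the counts outside Rn45s (percent) on Mir30d and on all other miRNAs, with 1 pair of bars per library. Mir30d averages 8.32% in controls, 2.03% with Miat guides and 10.03% with Mtdh guides, and the other miRNAs average 7.19%, 8.08% and 5.51%.

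The first comparison asked whether the libraries labelled Miat knockdown differ from the control in their miRNAs. Mir677, Mir6236, Mir92-1 and Mir20a were higher, while Mir30d, Mir92b and Mir181a-1 were lower. Mir92-1 rose 2.94-fold, from 6695 ± 819 to 19637 ± 6978 CPM (SD, n = 4 each), and Mir20a rose 3.77-fold, from 3758 ± 1295 to 13843 ± 10496 CPM. Both lie in the Mir17hg host transcript of the miR-17~92 cluster, a target of Myc and Mycn that promotes proliferation in Hedgehog-driven medulloblastoma. The cluster and its paralogues did not pass as a list (camera adjusted p = 0.0688), and Mir20a passed with sgMiat-6 alone. Mir677, in an intron of Atp5b, rose 4.13-fold, from 18145 ± 3674 to 75012 ± 13719 CPM, and Mir6236 rose 3.10-fold, from 20129 ± 3712 to 62202 ± 16222 CPM. Mir30d, scaled by TMM, was 3.10-fold lower in Miat libraries, at 173563 ± 7273 CPM against 538318 in controls. Mir92b, which neural progenitors express, was 4.75-fold lower, at 2051 ± 1959 against 9969 ± 2272 CPM, from 1 to 15 counts per Miat library. Mir181a-1, a member of a family that acts in neuronal and immune differentiation, was 1.67-fold lower, at 25823 ± 5491 against 43422 ± 3484 CPM.

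By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7 of 29 miRNAs passed an adjusted p of 0.05 in this comparison, 4 higher and 3 lower, and 9 had an unadjusted p under 0.05. The log2 fold change was 2.05 for Mir677 (SE 0.27, edgeR adjusted p = 5.24e-05), 1.63 for Mir6236 (SE 0.24, 6.94e-05) and -1.63 for Mir30d (SE 0.33, 0.00156). It was 1.55 for Mir92-1 (SE 0.32, edgeR adjusted p = 0.00167), -2.25 for Mir92b (SE 0.53, 0.00431), 1.91 for Mir20a (SE 0.49, 0.00716) and -0.74 for Mir181a-1 (SE 0.21, 0.0123). In 8 of the 29 miRNAs no Miat library overlapped a control library, where chance gives 2.86%, or 0.83 of them. Mir20a was called although its libraries overlap. Mir20a no longer passed without control 2, control 3 or Miat 6-2 (edgeR adjusted p = 0.0697, 0.0747 and 0.0932), with a log2 fold change of 1.23 without Miat 6-2. Mir92b moved to -3.19 without Miat 96-1, and without Miat 96-1 the count of calls rose to 12. Mir181a-1 no longer passed with library totals in place of TMM (-0.40, edgeR adjusted p = 0.493), and Mir92-1 and Mir20a no longer passed with all classes tested together (0.0908 and 0.110). With the Rn45s share as a covariate Mir677 and Mir6236 still passed. Mir30d (-1.11, edgeR adjusted p = 0.451), Mir92b (-1.24, 0.816), Mir92-1 (1.34, 0.436), Mir20a (2.69, 0.255) and Mir181a-1 (-0.067, 0.967) did not. Rn45s shares of control and Miat libraries did not overlap, so the covariate cannot separate the load from the group. Among miRNAs that did not pass, Mir93 had a log2 fold change of 1.90 (edgeR adjusted p = 0.0632), Mir6538 1.20 (0.0803), Mir3535 1.09 (0.149), Mir181a-2 -0.63 (0.158), Mir1981 1.06 (0.164), Mir351 -0.82 (0.228) and Mir99b -0.57 (0.305). Mir1843b, Mir9-2, Mir9-3, Mir181b-2, Mirlet7c-2 and Mirlet7a-1 lay between -0.34 and 0.51 (edgeR adjusted p from 0.610 to 0.798).

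**Figure D3:**
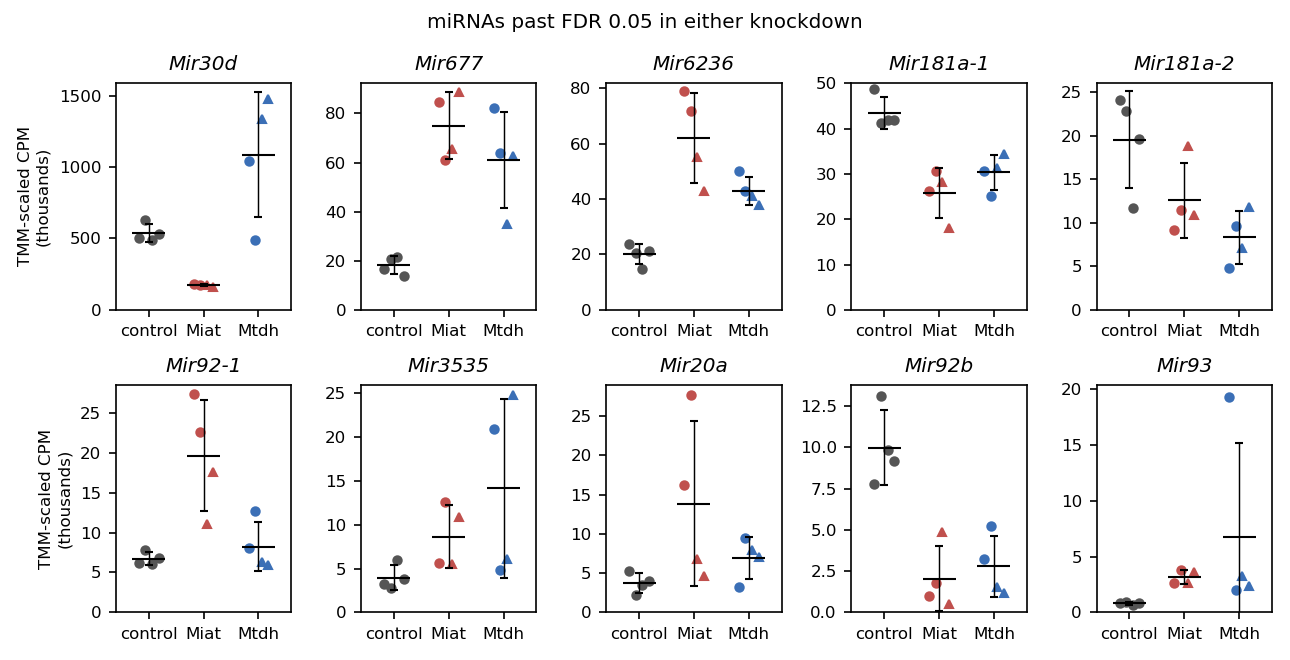
TMM-scaled counts per 1000000 counts of the tested miRNAs (CPM, linear axes in the unit printed on them) of the miRNAs past an adjusted p of 0.05 in either comparison with the control, with 1 point per library, lines for the mean and bars for the SD of 4 libraries, and triangles for the second guide of a target. Mir30d can exceed 1000000 because the scaling factors run from 0.523 to 1.62, and Mir677 averages 18145 CPM in controls, 75012 with Miat guides and 60962 with Mtdh guides.

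The second comparison asked the same of the libraries labelled Mtdh knockdown. Mir677 and Mir6236 were higher here too, while Mir92b and Mir181a-2 were lower. Mir677 rose 3.31-fold to 60962 ± 19559 CPM and Mir6236 rose 2.13-fold to 42970 ± 5113 CPM (SD, n = 4), against the control levels given above. Mir93 rose 5.80-fold, from 810 ± 127 to 6768 ± 8406 CPM. It lies in the replication gene Mcm7, in a paralogue of the miR-17~92 cluster that targets the cell cycle inhibitor p21, and its control level rests on 2 to 4 counts per library. Mir30d rose 2.02-fold and Mir3535, at a small nucleolar RNA locus in the nucleolin gene Ncl, rose 3.03-fold, from 3986 ± 1428 to 14191 ± 10206 CPM. Mir181a-2 was 2.29-fold lower, at 8368 ± 3042 against 19558 ± 5543 CPM, and Mir92b was 3.20-fold lower, at 2787 ± 1847 CPM, from 1 to 28 counts per Mtdh library.

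Here too 7 of 29 miRNAs passed in edgeR, 5 higher and 2 lower, and 10 had an unadjusted p under 0.05. The log2 fold change was 1.73 for Mir677 (SE 0.28, edgeR adjusted p = 4.24e-04), 1.09 for Mir6236 (SE 0.24, 0.00557), -1.20 for Mir181a-2 (SE 0.34, 0.0273) and 2.53 for Mir93 (SE 0.75, 0.0283). It was 1.01 for Mir30d (SE 0.32, edgeR adjusted p = 0.0366), -1.68 for Mir92b (SE 0.54, 0.0366) and 1.60 for Mir3535 (SE 0.55, 0.0426). In 7 of the 29 miRNAs no Mtdh library overlapped a control library, and among the calls the libraries of Mir30d, Mir181a-2 and Mir3535 did overlap. The count of calls fell to 2 without control 1, 2 or 4 or without Mtdh 1-1. It fell to 3 without control 3 and to 4 without Miat 6-2 or Mtdh 2-1. Mir181a-2, Mir93, Mir30d, Mir92b and Mir3535 all failed to pass without control 1, 2 or 4 or without Mtdh 1-1. Mir30d passed only when Mtdh 1-2 was the library left out, and failed without any other. Mir677 passed without each library in turn, and Mir6236 without each except control 3 (edgeR adjusted p = 0.0802). Without Mtdh 1-1 the log2 fold change of Mir93 was 1.62 (edgeR adjusted p = 0.103), and without Mtdh 2-2 that of Mir3535 was 0.81 (0.282). When library totals replaced TMM, the log2 fold change was 0.26 for Mir30d (edgeR adjusted p = 0.401), 0.51 for Mir6236 (0.283) and 0.91 for Mir3535 (0.239), and with all classes tested together Mir6236 was at 0.48 (0.403). Without Mtdh 1-2, Mir92b was at -2.45. With the Rn45s share as a covariate 0 of the 7 passed in edgeR, with 7 of 29 miRNAs at an unadjusted p under 0.05. Mir677 was then at 2.00 (edgeR adjusted p = 0.0650), Mir6236 at 1.46 (0.0843), Mir181a-2 at -0.89 (0.648) and Mir92b at -0.63 (0.844). The other calls had larger log2 fold changes and larger SEs with the covariate. Mir93 was at 3.73 (SE 1.43, edgeR adjusted p = 0.123), Mir3535 at 3.01 (SE 0.90, 0.0740) and Mir30d at 1.45 (SE 0.61, 0.147). Among miRNAs that did not pass, the log2 fold change was -0.53 for Mir181a-1 and -0.94 for Mir9-2 (edgeR adjusted p = 0.0938 each), 1.32 for Mir1981 (0.0958), and 0.86 for Mir30a and 1.01 for Mir20a (0.174 each). Mirlet7c-2, Mir9-1, Mir7-1, Mir7-2, Mir9-3, Mir181b-2, Mirlet7a-1 and Mir92-1 did not pass either, with Mir92-1 at 0.36 (edgeR adjusted p = 0.447) and Mirlet7a-1 at -0.93 (0.332).

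Mir30d separated the Miat from the Mtdh libraries. Set against the libraries labelled Miat knockdown, those labelled Mtdh knockdown had 6.25-fold more Mir30d (log2 fold change 2.64, SE 0.34, edgeR adjusted p = 3.30e-05) and 2.28-fold less Mir92-1 (-1.19, SE 0.33, 0.0396). These were the 2 calls of the direct comparison, 1 higher and 1 lower, and 5 miRNAs had an unadjusted p under 0.05. Mir92-1 did not pass with DESeq2 size factors (-1.19, edgeR adjusted p = 0.0542) or all classes tested together (-1.30, 0.0914). It also failed with totals without Mir30d (-0.93, 0.194) and with the Rn45s covariate (-1.18, 0.0617). It passed with library totals (-2.06, 0.00198) and upper-quartile factors (-1.41, 0.00815).

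Fold changes depended on how libraries were scaled. The median log2 fold change of all 29 miRNAs was -0.08 for Miat and -0.15 for Mtdh against control with TMM, and 0.25 and -0.59 with library totals alone. With library totals the Miat comparison had 7 higher and 2 lower calls and the Mtdh comparison 1 higher and 4 lower. With DESeq2 size factors these were 4 and 3 for Miat and 3 and 2 for Mtdh, and with upper-quartile factors 4 and 3 for Miat and 3 and 3 for Mtdh. With library totals that leave out Mir30d, they were 4 and 6 for Miat and 3 and 2 for Mtdh. The direct comparison had 1 higher and 14 lower calls with library totals, and 1 higher and 0 lower with DESeq2 size factors. No called miRNA changed direction under these scalings in the comparison that called it.

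Guides were then compared with the control one by one, to see which changes a single guide gave. Mir677 was higher with each of the 4 guides, by a log2 fold change of 2.01 with sgMiat-6, 2.09 with sgMiat-96, 1.99 with sgMtdh-1 and 1.38 with sgMtdh-2, and so was Mir6236, by 1.90, 1.29, 1.18 and 0.98. Mir30d was lower with both Miat guides, by -1.61 and -1.66, and passed with sgMtdh-2 (1.39, edgeR adjusted p = 0.00624) but not with sgMtdh-1 (0.50, 0.266). Mir92-1 was higher with both Miat guides, at 1.89 and 1.07. Mir20a was higher with sgMiat-6 (2.54, edgeR adjusted p = 3.16e-05) and did not pass with sgMiat-96 (0.65, 0.304). Mir351 was lower with sgMiat-6 (-2.46, edgeR adjusted p = 4.30e-06) and did not pass with sgMiat-96 (-0.04, 0.913). Tested directly, sgMiat-96 against sgMiat-6 gave 2 calls, Mir351 at 2.42 (edgeR adjusted p = 2.97e-05) and Mir20a at -1.89 (0.0129), and 8 miRNAs with an unadjusted p under 0.05.

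The guides gave 7 calls with sgMiat-6 (4 higher, 3 lower), 8 with sgMiat-96 (5 and 3), 5 with sgMtdh-1 (3 and 2) and 5 with sgMtdh-2 (4 and 1), with 2 libraries each. Of the 7 miRNAs called for Miat, 5 were called with both guides, namely Mir30d, Mir6236, Mir677, Mir92-1 and Mir92b, and of the 7 for Mtdh, 2 were, namely Mir6236 and Mir677. All 7 had the same sign with both guides in each case. The selection favours such agreement, since the pooled fit called them from the same libraries and both guides share the controls. In a fit that left out the sgMiat-6 libraries, Mir92-1 (0.93, edgeR adjusted p = 0.155) and Mir92b (-1.93, 0.1105) did not pass for Miat. Between sgMtdh-2 and sgMtdh-1 edgeR called 0 miRNAs with TMM and 0 with DESeq2 size factors, and 5 had an unadjusted p under 0.05.

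**Figure D4:**
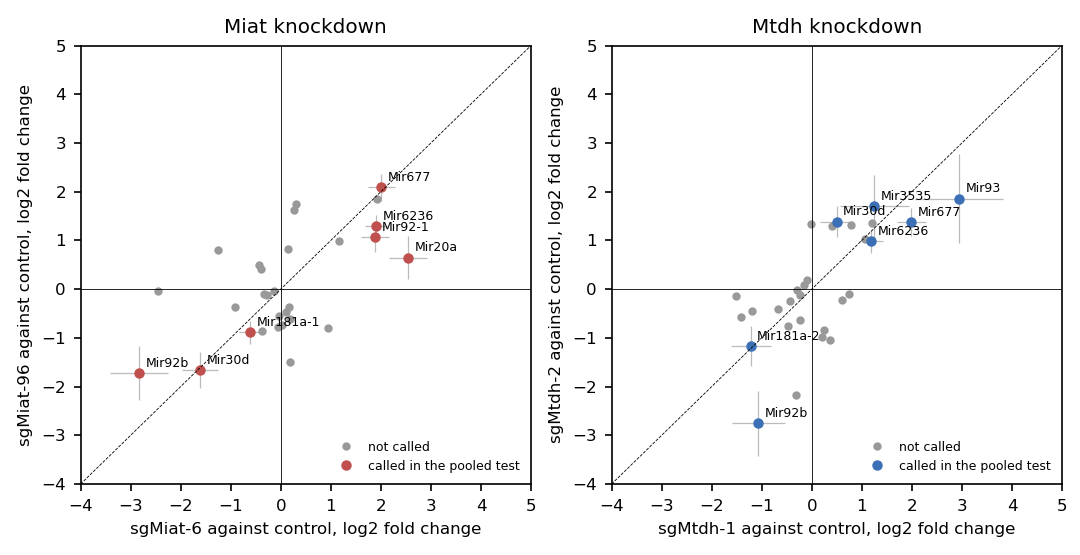
Log2 fold change against the control of each tested miRNA with the first guide (horizontal axis) and the second guide (vertical axis) of each target, with 1 point per miRNA, bars of 1 SE on the named ones called over both guides, and a dashed line where both guides are equal. Mir677 lies at 2.01 and 2.09 for the Miat guides and at 1.99 and 1.38 for the Mtdh guides.

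The libraries labelled Miat knockdown and those labelled Mtdh knockdown shared part of their differences from the control. All control libraries carry 1 guide, so a trait of the control set would appear in both comparisons. It cannot be told apart here from changes shared by both targets. With TMM, Mir677 and Mir6236 were higher and Mir92b lower in both, so 3 calls were shared in 1 direction. Mir30d, lower with Miat guides and higher with Mtdh guides, was the 1 call in opposite directions. The Mtdh call of Mir6236 was lost with library totals (0.51, edgeR adjusted p = 0.283). Independent lists with as many higher and lower calls would share 0.897 in 1 direction. Both comparisons use the same controls, and 100 simulated data sets with unchanged groups shared 0.01 calls on average and 1 at most. With no miRNA changed, few are called at all, so the simulation covers only the noise of shared controls. It gives no expectation for groups that each differ from the control. With the controls split so that each label had its own pair, 1 to 2 calls were shared, with a mean of 1.5. With the Rn45s share as a covariate 0 calls were shared, and 0 with no filter on low counts. The covariate cannot separate the load from the group in either comparison, since control shares did not overlap the others. Across miRNAs, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.652 and a Spearman correlation of 0.649, against means of 0.468 and 0.440 in the simulation, where the shared controls alone make them correlate. Simulated correlations reached 0.834 and 0.802, so the observed ones lay within that range. Their covariance was 0.671, against a mean of 0.118 and a highest value of 0.369 simulated. Neither group was changed in the simulation, so this gap does not tell shared changes from a trait of the controls.

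Groups of miRNAs fixed in advance were tested next, to see whether a programme moved as a whole. Of 18 lists, 4 had at least 3 tested members. Camera called 0 of the 8 list tests against the control at an adjusted p of 0.05 with its preset correlation of 0.01. Between Mtdh and Miat libraries none of the 4 lists passed either (camera adjusted p = 0.804 each). The miR-17~92 cluster and its paralogues had a median log2 fold change of 1.90 with Miat guides over the 3 tested members Mir92-1, Mir20a and Mir93 (camera adjusted p = 0.0688), with 2 members higher over all miRNAs tested and 3 when adjusted over the list alone. With Mtdh guides the median was 1.01 (camera adjusted p = 0.209), with 1 member called either way. The Mir181 copies, the tested members of the miRNAs reported to bind Miat, had a median of -0.43 with Miat guides (camera adjusted p = 0.193) and -0.47 with Mtdh guides (0.145), with 1 of 4 lower in each, and 1 when adjusted over the list alone. The let-7 family, which rises as progenitors mature, had medians of -0.13 and -0.23 over 5 members (camera adjusted p = 0.773 and 0.354) with 0 called. The neuronal differentiation list, represented by the Mir9 and Mir7 copies, had medians of -0.13 and -0.71 over 5 members (camera adjusted p = 0.746 and 0.354), also with 0 called. With Mtdh guides its members went opposite ways, with a mean of -0.067. Mir9-1, Mir9-2 and Mir9-3 were at -0.81, -0.94 and -0.71, and Mir7-1 and Mir7-2 at 1.17 and 0.95. The Mir9 copies had nearly the same counts in each library, such as 36, 36 and 34 in control 4. The Mir7 copies were close in most libraries. The 5 members are therefore not 5 separate measurements, and the list median and camera test rest on fewer.

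No camera result passed with an estimated correlation either, the lowest adjusted p being 0.163 with Miat guides and 0.228 with Mtdh guides. Fry, which asks only whether the members move on balance one way, gave adjusted p of 0.00304 and 0.0390 for the miR-17~92 list and 0.00919 and 0.0111 for the Miat partner list. Mir1981, the 1 tested member of the list processed without Drosha or Dicer, had log2 fold changes of 1.06 and 1.32 and did not pass (edgeR adjusted p = 0.164 and 0.0958). Adjusted over the list alone its count was 1 for Mtdh, which with 1 member is no adjustment. The other 13 lists had 0 tested members. Summed over the 4 libraries of the controls, of the Miat guides and of the Mtdh guides, the granule neuron and Hedgehog list held 52, 25 and 46 counts, the p53 list 59, 48 and 32, and the glial list 21, 18 and 21. The haematopoietic list held 1, 1 and 2 counts, the Dlk1-Dio3 list 0, 2 and 2, the endothelial list 0, 6 and 8, the mural list 0, 0 and 6, and the muscle list 0, 0 and 2. The Sfmbt2, pluripotency, erythroid, epithelial and liver lists held 0 counts in all 12 libraries.

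The called precursors were placed on GRCm38 by their RefSeq identifiers. Mir30d lies on chromosome 15 from 68341208 to 68341289, in an exon of the long non-coding RNA Gm20732. Mir677 lies on chromosome 10 from 128085286 to 128085363, at a locus that the annotation also gives as a small nucleolar RNA. Mir6236 lies on chromosome 9 from 110281287 to 110281409, in no annotated gene. Mir20a and Mir92-1 lie on chromosome 14 from 115044157 to 115044263 and from 115044427 to 115044506. Mir93 lies on chromosome 5 from 138165523 to 138165610, Mir92b on chromosome 3 from 89227116 to 89227198, and Mir3535 on chromosome 1 from 86351981 to 86352127. Mir181a-1 lies on chromosome 1 from 137966455 to 137966541, and Mir181a-2 on chromosome 2 from 38852735 to 38852810, opposite an intron of Nr6a1. Copies of one miRNA, such as Mir181a-1 and Mir181a-2, share the mature sequence of one arm, and how their shared reads were assigned is not given in the sources used here.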

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

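The tests of explanations in this part were chosen after the results were seen, and so was the choice of which other classes of RNA to look at.

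Mir30d held a lower share of miRNA counts with Miat guides, and its log2 fold change differed between Mtdh and Miat libraries by 2.64. Library scaling is argued against for the Miat libraries: over 6 scalings the log2 fold change nearest to 0 was -1.27, and the highest adjusted p was 0.00339; so is a loss of the whole miRNA fraction as the whole cause, since outside Rn45s the other miRNAs without Mir6538, Mir677 and Mir6236 changed by -0.40 (SE 0.0754) while Mir30d changed by -2.03 (SE 0.0818), though a smaller loss stays open. The load of ribosomal precursor is argued against only as the whole cause of the difference between Mtdh and Miat libraries. With it as a covariate, Mtdh libraries still exceeded Miat libraries in Mir30d by 2.55 (SE 0.353, edgeR adjusted p = 1.43e-04). For the lower Mir30d of Miat libraries against control, the load stays open as the whole cause or a part. The covariate moved that log2 fold change from -1.63 (SE 0.33) to -1.11 (SE 0.714, edgeR adjusted p = 0.451, range over all alternatives 5.69e-07 to 0.451), both a smaller fold and a larger SE. The Rn45s shares of control and Miat libraries did not overlap, so the covariate cannot separate the load from the group there. For the higher Mir30d with Mtdh guides, scaling may be the cause, since with library totals the log2 fold change was 0.26 (SE 0.223); an effect of either depletion on Mir30d was not tested apart from these.

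Mir6236 and Mir677 rose with Miat and with Mtdh guides relative to the tested miRNAs scaled by TMM, and both may count fragments of other RNAs. With Mtdh guides Mir6236 did not pass with library totals (0.51, edgeR adjusted p = 0.283) or with all classes tested together (0.48, 0.403). The ratio of Mir6236 to Rn45s differed from control by -0.058 on the log2 scale with Miat guides (SE 0.374, exact permutation p = 0.971), so ribosomal fragments counted on Mir6236 may be a source, but with the Rn45s share as a covariate its log2 fold change was 2.04 (SE 0.538) in place of 1.63, so the question stays open. With Mtdh guides it differed by -0.61 (SE 0.182, exact p = 0.0286), which argues against a constant ratio there. A rise of all small nucleolar fragments is argued against for Mir677, as its ratio to them was higher by 1.54 with Miat guides and by 1.34 with Mtdh guides (exact p = 0.0286 each, the lowest possible); the small nucleolar RNA annotated at the Mir677 locus itself stays open, as does an effect of the depletions.

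Miat was counted 49 and 30 times in Miat libraries 6-1 and 6-2, a signal outside the miRNA comparisons and above the 0 to 1 counts of the controls. Greater depth is argued against, because the lower bound of the ratio of rates was 5.80, and the sgMiat-96 libraries, also deeper than the controls, held 1 and 0 counts. Reads of the guide RNA itself stay open, since the other guide gave 1 count on Miat and the positions of the reads are not given in the sources used here. A mislabelled library was not tested, and fragments left after editing may also be a source.

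Some other differences between groups stood out. Mir92-1 differed between Mtdh and Miat libraries by -1.19 on the log2 scale. That call held with library totals and upper-quartile factors. It was lost with DESeq2 size factors, all classes tested together, totals without Mir30d and the Rn45s covariate (edgeR adjusted p from 0.0542 to 0.194). Between sgMiat-96 and sgMiat-6, Mir20a differed by -1.89 and Mir351 by 2.42.

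Single libraries lay far from the other 3 of their group in 10 of 111 groups by Dixon's test, where chance gives about 5.55. Mir181a-1 was at 48625 CPM in control 1, against 41233 to 41925 in the others. Mir6538 was at 504750 CPM in Miat 96-1, against 109650 to 120880, and Mir1843b was at 11390 CPM there, against 5124 to 5474. Mir30d took 15.4% of miRNA counts in Miat 96-1, against 22.5% to 22.8%. Mirlet7c-1 was at 8711 CPM in Miat 6-2, against 4055 to 4231. In Mtdh 1-1, Mir93 was at 19352 CPM, against 2047 to 3307, and Mirlet7i at 11289 CPM, against 1184 to 1526. Mir7-2 was at 10652 CPM in Mtdh 2-2, against 3164 to 3815. Rn45s took 82.7% of counts in Miat 96-2, against 70.2% to 71.5%, and other RNAs 5.59% there, against 7.98% to 8.40%.

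Single transcripts of other classes, which the miRNA comparisons do not use and which were picked for their large rise, also stood out. The log2 fold change with Miat guides was 5.79 for Rprl3, 4.88 for Serf2, 3.93 for 5730488B01Rik and 3.06 for Snora81. With Mtdh guides it was 5.53 for Serf2, 5.16 for Rprl3, 4.44 for 5730488B01Rik and 3.71 for Scarna2.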

How the results depend on the processing

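Alternatives chosen after seeing the data were the exclusion of 3 shallow libraries, library totals without Mir30d, exclusion of small nucleolar loci, the Rn45s covariate, fry, the libraries left out for guides, overlap and class shares, the other alternatives for the overlap, and, for the named miRNAs, upper-quartile factors, guide as a random effect, only 2 groups, the robust fit, the fold minimum, copies summed, no filter and each guide left out. No called log2 fold change changed direction under any alternative that gave it a value. Of the values of named miRNAs, 815 for Miat and 667 for Mtdh kept their side of the threshold, 18 and 17 crossed to pass, and 26 and 105 no longer passed. Mir677 passed in 34 of 34 alternatives for Miat and 31 of 34 for Mtdh, Mir6236 in 35 of 35 and 28 of 35, Mir30d in 34 of 35 and 7 of 35, and Mir92b in 32 of 35 and 20 of 35. For Miat alone, Mir92-1 and Mir181a-1 passed in 28 of 34 and Mir20a in 25 of 35. For Mtdh alone, Mir181a-2 passed in 21 of 34, Mir93 in 20 of 34 and Mir3535 in 9 of 34. The 7 calls for Miat became 3 with the last number of the library name as a replicate block, 4 without sgMiat-6 and 2 with the Rn45s covariate, with 6 to 12 when each library was left out. The 7 calls for Mtdh became 0 with no filter and 0 with a mean CPM of at least 10, where 270 miRNAs share the adjustment; 17 and 17 miRNAs had an unadjusted edgeR p under 0.05. They became 2 with guide as a random effect in voom (correlation 0.262), 1 with the block, 4 without sgMiat-6, 4 without sgMtdh-1, 3 without sgMtdh-2, 2 without the 3 libraries under 2000 miRNA counts, 4 without small nucleolar loci and 0 with the Rn45s covariate (7 at an unadjusted p under 0.05). With each library left out they were 2 to 8. The 2 calls between Mtdh and Miat libraries became 15 with library totals, of which 14 were lower, and 4 without sgMtdh-1. They became 1 with DESeq2 size factors, DESeq2, voom, voom with guide as a random effect, only 2 groups, the block, sgMiat-6 left out, sgMtdh-2 left out, all classes together, copies summed, the 3 libraries left out, totals without Mir30d, small nucleolar loci left out and the Rn45s covariate, and 1 to 4 with each library left out. With no filter the guides gave 3 (sgMiat-96), 1 (sgMtdh-1) and 3 (sgMtdh-2) calls, and 1 between the Miat guides. With each library left out they gave 7 to 14 (sgMiat-6), 4 to 10 (sgMiat-96), 1 to 10 (sgMtdh-1) and 2 to 7 (sgMtdh-2), with 1 to 3 between the Miat guides and 0 to 1 between the Mtdh guides, and a lone library was assumed to vary like the others. The 3 shared calls became 1.5 with split controls and 5 at an unadjusted p under 0.05, 0 with no filter, 0 with a mean CPM of at least 10, 5 with the guide fit, 5 with only 2 groups, 1 with the block and 0 with the Rn45s covariate, and were 2 to 4 with each library left out. The 0 list calls became 3 with a mean CPM of at least 10, 3 with the guide fit and 4 with fry, and were 0 to 3 with each library left out. Without Rn45s, differences in share changed sign for miRNAs with Mtdh guides (0.0372 points), other RNAs with Miat guides (8.10) and Mtdh guides (10.4), and small nucleolar RNAs with Miat guides (2.69). The cause of these changes was not tested. The last numbers of the library names gave no clear pairing, since residuals correlated between -0.38 and 0.46 across guides. With 1 deviation per guide, this check cannot exclude a pairing. The ratio of precursor arms, and DESeq2 or voom for the lists, which camera already takes from voom, were not run. Depth limits the rest: 29 of 270 miRNAs with counts could be tested.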

Other observations

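Small RNAs of other classes moved as well, in a fit of all 147 transcripts with enough counts; these transcripts were singled out after their values were seen. Rprl3 and Rpph1, both copies or relatives of the RNA of RNase P, rose with Miat and with Mtdh guides, Rpph1 by 2.83-fold with Miat guides (log2 SE 0.34, edgeR adjusted p = 0.00650, n = 4) and 5.43-fold with Mtdh guides (log2 SE 0.35, 3.99e-04). The log2 fold change of Rprl3 was 6.77 with sgMiat-96 (edgeR adjusted p = 1.33e-07) and 1.34 with sgMiat-6 (0.0640). Scarna2, a Cajal body RNA that guides modification of the spliceosomal U2 RNA, rose by 2.42 with Miat guides (SE 0.75, edgeR adjusted p = 0.0398) and 3.71 with Mtdh guides (SE 0.75, 0.00263). Serf2 and 5730488B01Rik also rose in both, from 0 to 3 counts per control library.

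Other transcripts moved with the guides of 1 target. Snora81, which guides pseudouridine formation in ribosomal RNA from an intron of Eif4a2, rose 8.32-fold with Miat guides (log2 fold change 3.06, SE 0.56, edgeR adjusted p = 0.00190) and stood at -0.11 with Mtdh guides, a difference of -3.17 (SE 0.57, edgeR adjusted p = 0.00311). It rose with both Miat guides, by 2.41 with sgMiat-6 and 3.51 with sgMiat-96. Scarna6 fell with Miat guides (-1.74, SE 0.31, edgeR adjusted p = 0.00151) and differed between Mtdh and Miat libraries by 1.28 (0.0255). Scarna17 fell with Mtdh guides (-2.81, SE 0.52, edgeR adjusted p = 0.00139) and differed by -2.15 (0.0255), from 1 to 5 counts per Mtdh library. Tug1, a long non-coding RNA of neural tissue, rose with Miat guides (1.53, SE 0.40, edgeR adjusted p = 0.0145), while its difference between Mtdh and Miat libraries did not pass (-0.91, 0.174). In all, 21 transcripts passed for Miat (16 higher, 5 lower) and 17 for Mtdh (12 higher, 5 lower).

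Calls in other splits of the libraries into groups of 4 were counted, with the number of calls already found as the mark to reach. For the 7 miRNAs called with Miat guides, 1 of 35 splits gave as many, the real one, and the highest other split gave 1. That is the lowest share 35 splits can give. The splits treat the libraries as independent, which the labels do not state. Libraries are also nested in guides, 2 per target and 1 for the control, with a guide correlation of 0.262 in voom. The splits take no account of guides, so they cannot exclude chance differences between them. For the 7 called with Mtdh guides it was again 1 of 35, with 1 as the highest other, and for the 2 called between Mtdh and Miat libraries 1 of 35, with 1 as the highest other. In the fit of all classes, the real splits gave 21 for Miat and 17 for Mtdh, each the 1 of 35 splits with as many, with 2 and 0 as the highest others. For the 6 transcripts of all classes called between Mtdh and Miat libraries, 4 of 35 splits gave as many and the highest other gave 16, so chance cannot be excluded there even with independent libraries. That split put Mtdh 1-2 with Miat 6-1, 6-2 and 96-1 and may reflect a structure of the libraries other than the group, which was not tested.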
